A study of Rattus norvegicus with 30 samples.

How the data were processed

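Rat liver was sampled after removal of 70% of the liver (partial hepatectomy) or after a sham laparotomy, in which the abdomen was opened and the liver left whole. Per the labels, the animals were male Wistar rats, total RNA was isolated with a column kit that retains small RNA (miRNeasy), and each time had 3 biological replicates. miRNAs were measured on a 1-colour microfluidic chip (febit), on which the captured miRNA primes an enzymatic extension that adds biotin, per the labels' protocols. The hepatectomy groups were 0, 2, 6, 12, 24 and 48 h and 5 d, and the sham groups were 12, 24 and 48 h, which made 10 groups and 30 arrays.

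The deposited scanner tables give raw spot intensity on a linear scale for every array. Background-subtracted intensity was given per spot for the sham arrays only, and as a median per miRNA for all arrays. In the hepatectomy and joint fits, the setting with the authors' background-subtracted values used these medians. The 21 hepatectomy arrays and the 9 sham arrays stood in separate tables with different chip layouts, 15 spots per probe name in the first and 22 in the second. The authors' background-subtracted median was the median of the raw spots minus 1 constant per array, as a comparison of the 2 showed. The authors also deposited a processed value per miRNA on a log2 scale. It covered 323 miRNAs and no star strand, so counts with the processed values are over fewer names. Set against the scanner values, it was a generalized log2 of the background-subtracted intensity with a common constant of 4.84 added. The image software, and how these constants were chosen, are not given in the sources used here. Between the raw and processed tables, the replicate letters of 4 columns were exchanged within a group (replicates 1 and 2 at 2 h, replicates 1 and 3 at 48 h), which changed no group. Which animal these 4 arrays came from is not settled. Replicate numbers here follow the raw tables, so the replicate block, the pairing check and the naming of these arrays when left out depend on that choice.

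The raw intensities were background-corrected with normexp (offset 50), log2 transformed, normalized between arrays by quantiles and averaged over the spots of one probe name, with limma 3.58.1 in R 4.3.3. The hepatectomy fit held 388 rat miRNA names, 58 of them star strands. The sham fit held 680 names, and the joint fit of both operations 376 shared names. In the joint fit, spots were averaged before quantile normalization because the layouts differ. Missing spots made up 0.585% of the hepatectomy table and 0.811% of the sham table, and were left out of the averages. Of the hepatectomy spots, 2 lay at or near full scale and were kept. Names followed the chip design. Of the 330 names that are not star strands, 320 matched a gene table of the rat assembly GRCr8, which was used for names and for which genes neighbour each other. The build behind the probes is not given in the sources used here, so no coordinates are printed.

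The number of arrays limited the precision. The median standard error of a log2 difference was 0.192 between hepatectomy times, 0.166 between operations, 0.235 for a difference in change and 0.105 between sham times. Linear models with empirical Bayes moderation (lmFit and eBayes) were fitted over all groups of a fit, with 14 residual degrees of freedom for hepatectomy, 6 for sham and 20 for the joint fit. Each hepatectomy time was compared with 0 h, all times together were compared by limma's moderated F test, and sham times were compared among themselves. Hepatectomy was compared with sham at 12, 24 and 48 h, and the change between times was compared between operations. P values were two-sided and adjusted by Benjamini-Hochberg over the names of each comparison, with a threshold of 0.05. All adjusted p values for single miRNAs come from limma. Because operation and chip layout were the same split of the arrays, the direct comparison of operations cannot tell them apart. A constant offset per miRNA between layouts cancels in the comparison of changes, but whether probes of one name have identical sequences in both layouts is not given in the sources used here, and a response that differs in slope would not cancel.

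The miRNAs named in the text followed a rule. They were the 5 largest rises and 5 largest falls past the threshold whose mean level lay above the median of all miRNAs and whose arrays did not overlap between groups (10 and 10 at 24 h). They were the 10 smallest p values of an F test and, where nothing passed, the 3 smallest p values. A fixed set of 11 was added for every hepatectomy comparison: miR-21, miR-122, miR-221, miR-222, miR-34a, miR-26a, miR-16, miR-17-5p, let-7a, miR-223 and miR-1. The 20 lists were liver-enriched miRNAs, let-7, miR-17/20/93, miR-15/16, miR-34 with miR-449, miR-29, miR-30, miR-23/24/27, miR-21 with miR-221 and miR-222, miR-181, miR-26, the biliary and epithelial miR-200 family, leukocyte, erythroid, endothelial and mesenchymal, muscle, neural, embryonic miR-290, the imprinted Dlk1-Dio3 cluster and star strands. The design, rule, lists and alternatives were set before the data were examined, except the 5 alternatives named below. A level above the median of all miRNAs does not show signal above background, which was not tested for single miRNAs.

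The 18 lists with 3 or more measured members were tested with camera at its preset correlation between genes of 0.01, again with an estimated correlation, and with fry, which tests whether a list's members move on balance one way and does not compare them with other miRNAs. Adjustment was over the lists of each comparison. The miR-26 and erythroid lists were described by their members. Tests of single values over arrays were exact permutation tests, or permutation tests with 100000 resamples.

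The tests of single miRNAs in 3 comparisons, both F tests and the let-7 list test at 24 h against 0 h were tested on 50 simulated datasets each, with 20 changed miRNAs per size. The other comparisons and lists were not simulated. For single miRNAs and F tests, noise was drawn independently for each miRNA and array, so deviations shared across an array were absent. The shares of single-miRNA calls below therefore need not hold for the real arrays. For the let-7 list, whole arrays of residuals were dealt out anew, which keeps such deviations. For 24 h against 0 h, changes of 0.5, 1 and 1.5 on the log2 scale were called in 24.8%, 72.8% and 92.3% of cases, and 4.48% of calls were unchanged miRNAs. For hepatectomy against sham at 24 h the shares were 30.9%, 74.8% and 91.7%, with 5.51% of calls unchanged, and for the difference in change from 12 to 24 h they were 10%, 45.8% and 72.1%, with 5.40%. A let-7 list with no simulated change was called by camera at the preset correlation in 26% of datasets, and in 0% with an estimated correlation or with fry. With a simulated change of -1, it was called in 100% by camera at the preset correlation, 90% with an estimated one and 100% by fry. The preset-correlation list calls were read with this in mind.

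Alternatives were the authors' background-subtracted and processed values, no background correction, centring on the median or the 75th percentile, no normalization, the median of spots, only miRNAs above the median level, array weights, fits of only the compared groups, each table processed on its own, the replicate number as a block, and each array left out in turn. Chosen after seeing the data were a block for background level, the high-background arrays alone, a fit without the 4 hepatectomy arrays of weakest signal span, and signal span as a covariate in either fit. A chip or slide block was not run because none is named in the sources used here.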

Results

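The series followed miRNAs in rat liver over the days after removal of 70% of the organ, an operation after which the remaining lobes regrow. Sham laparotomy at 12, 24 and 48 h served as the control for surgery. Each of the 10 groups held 3 arrays, labelled as biological replicates. The median raw intensity of the hepatectomy arrays was 544 to 608 in 8 arrays and 976 to 1328 in 13, and all 3 arrays at 24 h were among the brighter 13. Sham arrays had medians of 296 to 408. Signal span, the 95th percentile minus the median of log2 signal on an array, was 1.89 ± 0.44 (SD, n = 3) at 0 h and 1.11 ± 0.51 at 24 h. That difference of -0.79 had an exact permutation p of 0.2, where 3 against 3 arrays allow no p below 0.1. Over all 7 hepatectomy times, the permutation p was 0.583 for span, 0.896 for the array median and 0.882 for the 75th percentile.

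**Figure D1:**
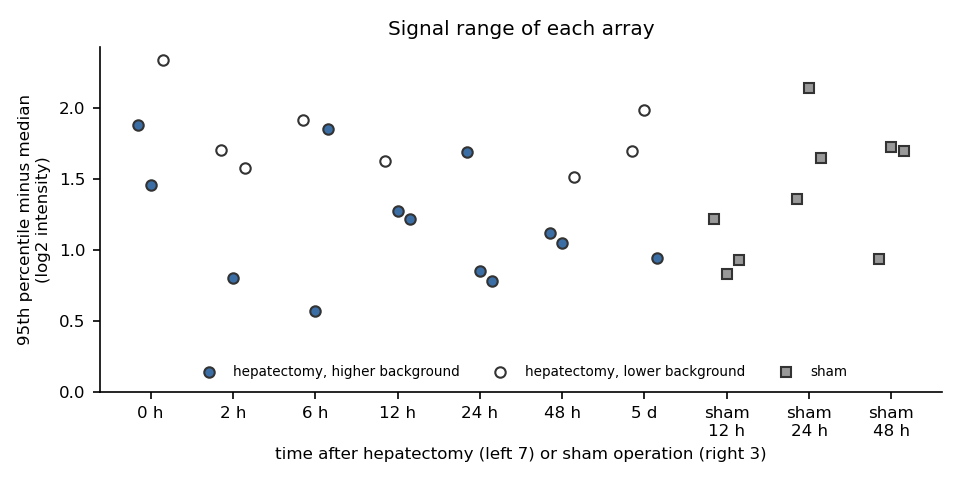
Signal span of each array (log2, 95th percentile minus median, vertical axis) by group (horizontal axis), with markers separating arrays of low and high background and sham arrays. The hepatectomy arrays with the weakest spans were replicate 2 at 2 h (0.80), replicate 2 at 6 h (0.57) and replicates 2 and 3 at 24 h (0.85 and 0.78). Span was taken over 388 names on hepatectomy arrays and 680 on sham arrays, so spans of the operations are not directly comparable.

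The time course asked which miRNAs differed among the 7 hepatectomy times. miR-26a, which represses cyclins and the methyltransferase Ezh2, was at a mean log2 level of 11.30 ± 0.16 (SD, n = 3) at 0 h, 10.19 ± 0.67 at 12 h, 9.34 ± 0.62 at 24 h, 10.34 ± 0.28 at 48 h and 10.99 ± 0.03 at 5 d (adjusted p = 0.00252, limma's moderated F test). let-7c, of a family that represses Ras, Hmga2 and Lin28, went from 9.42 ± 0.11 at 0 h to 7.91 ± 0.35 at 24 h and 8.70 at 5 d (adjusted p = 0.0125). let-7d (adjusted p = 0.0135) was at 9.53 ± 0.07 and 8.03 ± 0.05 at 0 and 24 h. miR-125b-5p, the mammalian relative of worm lin-4, was at 10.09 ± 0.07 and 8.50 ± 0.38 (adjusted p = 0.0135). miR-532-3p, from an intron of Clcn5, was at 9.12 ± 0.13 at 0 h and between 8.07 and 8.26 at every later time (adjusted p = 0.0173). let-7f and let-7a (both adjusted p = 0.0173), miR-100 (0.0316) and miR-99a (0.0487), a pair that represses mTOR, also changed. These 9 of 388 miRNAs passed the test, with 43 at an unadjusted p under 0.05. The count was 4 without replicate 1 at 0 h, 3 without replicate 3 at 0 h, 14 without replicate 2 at 6 h and 5 without replicate 3 at 24 h. It was 4 with median centring, 2 with 75th percentile centring, and 0 with no normalization and with the authors' background-subtracted values. It was 87 with array weights and 38 with signal span as a covariate. Every comparison with 0 h below shares the same 3 arrays at 0 h, so their results are not independent of one another. For miR-532-3p, which differed little among the later times, a deviation of those 3 arrays cannot be told apart from a fall.

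**Figure D2:**
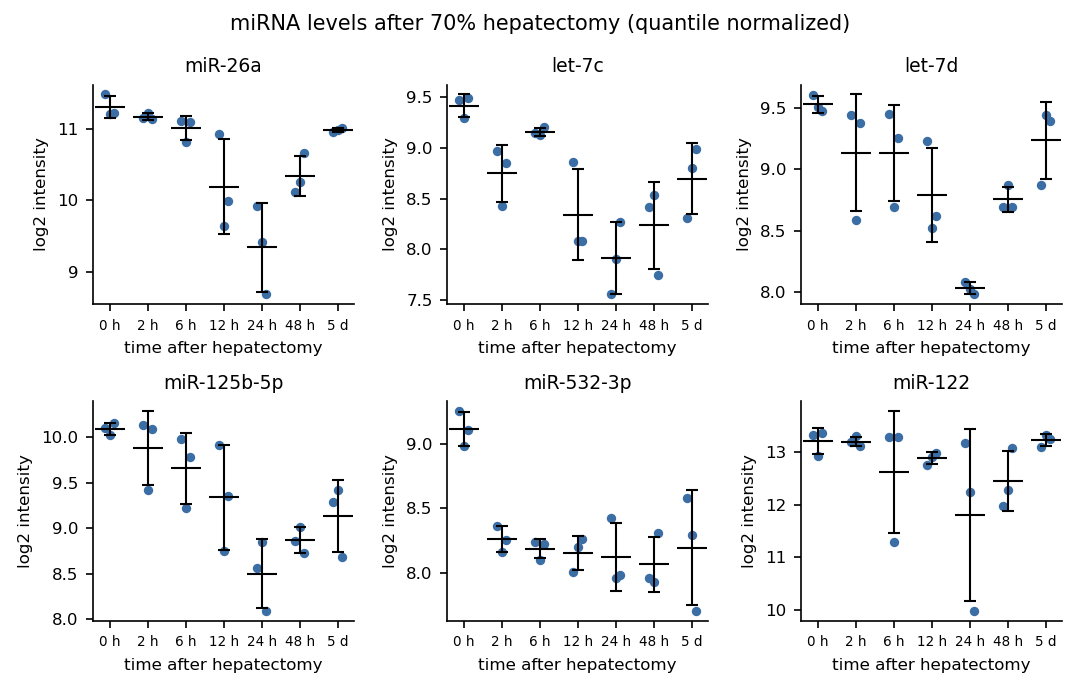
Normalized log2 level (vertical axis) of miR-26a, let-7c, let-7d, miR-125b-5p, miR-532-3p and miR-122 at 7 times after hepatectomy (horizontal axis), with a point per array and the mean with SD of 3 arrays per time. miR-26a went from 11.30 at 0 h to 9.34 at 24 h and 10.99 at 5 d, while the arrays of miR-122 at 24 h were spread with an SD of 1.63.

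At 2 h no single miRNA passed the test against 0 h. The smallest p values were those of miR-532-3p (log2 difference -0.86, SE 0.19, adjusted p = 0.0677, n = 3 per group), miR-146a, which NF-kB induces (-0.75, SE 0.19, adjusted p = 0.171), and miR-667 of the imprinted Dlk1-Dio3 cluster (-0.95, SE 0.26, adjusted p = 0.213). The let-7 list fell as a set (median -0.43, -1.04 to -0.38 over 5 scalings, camera adjusted p = 8.94e-05), with adjusted p = 0.398 with an estimated correlation and 0.328 by fry. None of its 8 members passed over all miRNAs, and 3 fell when adjusted over the list alone. No other list passed, though the miR-30 list did with median centring (camera adjusted p = 0.0453, against adjusted p = 0.398 with an estimated correlation on the quantile-normalized values). Among the 11 fixed miRNAs, miR-223, a myeloid miRNA, was at -0.63 (adjusted p = 0.442). miR-21, which represses Pdcd4, was at -0.29 (adjusted p = 0.988), miR-122, the most abundant hepatocyte miRNA, at -0.01 and miR-222 at -0.02, both with adjusted p = 0.999. miR-221, which with miR-222 represses the inhibitor p27, was at 0.23 (adjusted p = 0.948) and miR-34a, a p53 target, at 0.10 (adjusted p = 0.987). miR-26a (-0.13, adjusted p = 0.999), miR-16 (0.25, 0.988), miR-17-5p (-0.29, 0.969), let-7a (-0.35, 0.957) and miR-1 (0.18, 0.98) completed the set. limma called 0 of 388, with 24 at an unadjusted p under 0.05, and 53 (13.7%) did not overlap between the groups, where chance gives 10%. Here and below, that 10% is an average. Deviations shared across an array can move the share far from it, so the share is not a test. Without replicate 2 at 0 h, 4 miRNAs were called. miR-532-3p passed under 7 of the other 15 settings, 75th percentile centring among them (-1.03, adjusted p = 0.0211), and its adjusted p over all 15 was 0.000758 to 0.94.

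At 6 h miR-532-3p fell (log2 difference -0.93, SE 0.19, adjusted p = 0.0283, n = 3 per group), by 1.91 times on the linear scale. It was the 1 call among 388 miRNAs, with 26 at an unadjusted p under 0.05. As miR-532-3p stood at a similar level at every later time, a deviation of the 0 h arrays would give the same fall. The let-7 list fell as a set (median -0.26, camera adjusted p = 0.0146) with no member past the test, adjusted p = 0.689 with an estimated correlation and 0.579 by fry, and a median of -0.73 to -0.15 over 5 scalings. No other list passed. In the fixed set, miR-122 was at -0.58 (adjusted p = 0.91), miR-223 at -0.46 (0.779), miR-21 at -0.35 (0.978), miR-26a at -0.29 (0.91), let-7a at -0.27 (0.868) and miR-17-5p at -0.20 (0.915). miR-1, a muscle miRNA, was at 0.29 (adjusted p = 0.868), miR-221 at 0.23 (0.8), miR-222 at 0.15 (0.978), miR-34a at -0.08 (0.978) and miR-16 at -0.13 (0.988). Groups did not overlap for 52 miRNAs (13.4%), where chance gives 10%. The call was lost without replicate 1 or 3 at 0 h and without any 1 of the 3 arrays at 6 h, where miR-532-3p had adjusted p = 0.0858 without replicate 2. The count was 0 without replicates 1 or 3 of either time, and 4 without replicate 2 at 0 h. miR-532-3p kept its call under 8 of the other 15 settings, and was at -0.66 (adjusted p = 0.752) with no normalization and had adjusted p = 0.302 with the authors' processed values. With array weights 2 were higher and 12 lower, and with signal span as a covariate 7 and 6.

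At 12 h, 9 miRNAs fell and 2 rose against 0 h. let-7f fell most (log2 difference -1.60, SE 0.28, adjusted p = 0.00597, n = 3 per group). miR-483, encoded in an intron of Igf2, fell by 1.37 (SE 0.33, adjusted p = 0.0267), and miR-26a (-1.11, SE 0.28, adjusted p = 0.0324) and let-7c (-1.08, SE 0.24, adjusted p = 0.0179) fell too. miR-100 (-0.99, SE 0.19, adjusted p = 0.00642), miR-532-3p (-0.97, adjusted p = 0.00642), let-7a (-0.90, adjusted p = 0.0376), miR-146a (-0.85, adjusted p = 0.0179) and miR-125a-5p (-0.63, adjusted p = 0.0124) were the other falls, miR-532-3p, miR-146a and miR-125a-5p being named after their values were seen. The rises were miR-142-5p of haematopoietic cells (0.56, SE 0.14, adjusted p = 0.0376) and the star strand of miR-204 (miR-204*, 0.51, SE 0.13, adjusted p = 0.0384).

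As a list at 12 h, let-7 had 3 of 8 members that fell and 5 that did not pass, and 7 fell when adjusted over the list alone (median -0.81, camera adjusted p = 2.86e-07, adjusted p = 0.189 with an estimated correlation and 0.0165 by fry). Its median was -1.67 to -0.40 over 5 scalings. The miR-30 list was lower as a set (median -0.39, camera adjusted p = 0.0329), with 3 of 5 members lower when adjusted over the list alone and 0 over all miRNAs. Its median was 0.00 with no normalization, where the median of all miRNAs was positive. The list had adjusted p = 0.575 with an estimated correlation and 0.14 by fry. Of the rest of the fixed set, miR-223 was at -0.73 (adjusted p = 0.0991), miR-21 at -0.46 (0.659), miR-17-5p at -0.35 (0.453), miR-122 at -0.32 (0.82) and miR-34a at -0.20 (0.559). miR-222 was at 0.26 (adjusted p = 0.565), miR-221 at 0.16 (0.638), miR-1 at 0.16 (0.8) and miR-16 at 0.05 (0.961). Of 388 miRNAs, 73 had an unadjusted p under 0.05 and 98 (25.3%) did not overlap, where chance gives 10%. Against 2 higher and 9 lower here, the split was 0 and 6 with either centring and 1 and 16 with the authors' processed values, but 37 and 25 with signal span as a covariate, 27 and 35 with array weights and 12 and 16 with only the compared groups. It was 0 and 13 with the median of spots, 0 and 7 with no background correction, 0 and 11 on the high-background arrays alone and 0 and 1 with the authors' background-subtracted values, and no miRNA was called with no normalization. Either centring ended the calls of miR-26a, let-7a, miR-142-5p and miR-204* (adjusted p 0.0782 to 0.153), and miR-223 was at -2.34 (adjusted p = 0.0358) with the authors' processed values. The count of 11 was 1 without replicate 1 and 5 without replicate 3 at 0 h, and 17, 2 and 4 without replicates 1, 2 and 3 at 12 h. Without each of the 6 arrays in turn, let-7f stayed past the threshold, while miR-100 was lost without replicate 1 at 0 h or 2 at 12 h (highest adjusted p = 0.0661). miR-483, miR-26a, let-7c and let-7a were lost without replicate 1 or 3 at 0 h or 2 or 3 at 12 h, and both rises also without replicate 2 at 0 h (highest adjusted p = 0.276).

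At 24 h, when DNA synthesis in hepatocytes is known to peak after this operation in rats, 19 miRNAs fell and 11 rose against 0 h. miR-26a fell most (log2 difference -1.97, SE 0.28, adjusted p = 0.000298, n = 3 per group), by 3.90 times on the linear scale, and miR-125b-5p fell by 3.00 times (-1.59, SE 0.28, adjusted p = 0.00136). Of the let-7 family, let-7c (-1.51, SE 0.24, adjusted p = 0.0007), let-7d (-1.49, SE 0.23, adjusted p = 0.000581), let-7f (-1.36, SE 0.28, adjusted p = 0.00498), let-7a (-1.16, SE 0.23, adjusted p = 0.00431) and let-7b (-1.10, SE 0.24, adjusted p = 0.00843) fell. miR-126 of endothelial cells, encoded in Egfl7 (-1.52, SE 0.36, adjusted p = 0.0113), miR-145 of smooth muscle and mesenchymal cells (-1.12, SE 0.28, adjusted p = 0.015) and miR-483 (-1.11, SE 0.33, adjusted p = 0.042) fell as well. The largest rise was that of miR-153, a neural miRNA (0.87, SE 0.18, adjusted p = 0.00629). It was followed by miR-883 (0.70, adjusted p = 0.042), miR-489 from an intron of Calcr (0.67, adjusted p = 0.0113) and miR-448 from an intron of Htr2c (0.60, adjusted p = 0.015). Next were miR-298 (0.52, 0.042), miR-32 (0.50, 0.042), miR-376b-3p (0.50, 0.029) and miR-142-5p (0.49, 0.042). A level above the median of all miRNAs need not be far above background. The median raw spot at 0 h was 1080, 1120 and 544, where the authors subtracted 1008, 1072 and 464. At 24 h it was 1240, 984 and 1024, where they subtracted 960, 840 and 912. Whether the risen miRNAs stood above background was not tested, so their rises are not read as induction.

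By list at 24 h, 7 of 8 let-7 members fell and 1 did not pass, and 7 fell adjusted over the list alone. The list's median was -1.13 (camera adjusted p = 1.44e-08, adjusted p = 0.111 with an estimated correlation and 0.00122 by fry), and was negative under all 5 scalings compared (-2.56 to -0.97). The let-7 members are nearly identical in sequence, and cross-hybridisation between their probes was not tested. In the miR-30 list (median -0.79), 1 of 5 members, miR-30d, fell (-1.10, SE 0.27, adjusted p = 0.015), and 3 fell adjusted over the list alone. In the miR-23/24/27 list (median -0.83), 0 of 5 passed over all miRNAs and 4 were lower adjusted over the list alone, with miR-27b at -1.13 (adjusted p = 0.0665) and miR-23a at -0.91 (adjusted p = 0.0707). Both lists had a camera adjusted p of 0.00569, and an adjusted p = 0.373 with an estimated correlation, while fry gave 0.0254 for miR-30 and 0.0831 for miR-23/24/27. Neither median changed sign over 5 scalings (-1.31 to -0.66 and -1.75 to -0.80). Both measured members of the miR-26 list were lower adjusted over the list alone, with miR-26b at -0.61 (adjusted p = 0.0707). In the endothelial and mesenchymal list, 2 of 8 members fell, miR-126 and miR-145 (list median -0.19, camera adjusted p = 0.128). In the leukocyte list, miR-142-5p rose and miR-146a fell (-0.68, SE 0.19, adjusted p = 0.039) among 7 (list median -0.13, camera adjusted p = 0.918). In the neural list, 1 of 13, miR-153, rose (list median 0.26, camera adjusted p = 0.128), and fry gave the set an adjusted p of 0.0112, against adjusted p = 0.373 with an estimated correlation. Of 42 imprinted Dlk1-Dio3 miRNAs, 1, miR-376b-3p, rose and none adjusted over the list alone (list median 0.13, camera adjusted p = 0.188). No star strand passed among 58, with a list median of 0.13 (camera adjusted p = 0.184), a fry adjusted p of 0.00788 and an adjusted p = 0.373 with an estimated correlation.

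The other lists had no member past the test at 24 h. For the liver-enriched list (median -0.30, camera adjusted p = 0.253), miR-122 was at -1.41 (adjusted p = 0.105) and miR-148b-3p at 0.52 (adjusted p = 0.127). The medians and camera adjusted p values were -0.17 and 0.301 for miR-17/20/93, -0.32 and 0.128 for miR-29, 0.22 and 0.918 for miR-15/16, and 0.27 and 0.918 for miR-21 with miR-221 and miR-222. They were 0.03, 0.00, 0.13 and 0.05 for the miR-34 with miR-449, miR-181, muscle and embryonic lists and -0.04 for the biliary and epithelial list, each with camera adjusted p = 0.919. The erythroid pair, miR-144 (0.29, adjusted p = 0.274) and miR-451 (-0.06, adjusted p = 0.889), did not pass. Median, mean and test differed in sign for miR-21 with miR-221 and miR-222, miR-34 with miR-449, miR-181, muscle and the biliary list. The liver-enriched, miR-17/20/93, leukocyte, endothelial, miR-34 with miR-449, miR-181, muscle, biliary and embryonic medians changed sign or reached 0 under at least 1 scaling, so no direction is given for them. For the fixed set, miR-21 was at -0.77 (SE 0.46, adjusted p = 0.295), miR-223 at -0.60 (0.112), miR-17-5p at -0.59 (0.0948), miR-16 at -0.30 (0.732) and miR-34a at -0.24 (0.345). miR-222 was at 0.38 (adjusted p = 0.232), miR-221 at 0.27 (0.246) and miR-1 at 0.15 (0.76), the last at -0.35 with signal span as a covariate.

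The 30 calls at 24 h were made among 388 miRNAs, 105 of which had an unadjusted p under 0.05. Groups did not overlap for 128 miRNAs (33.0%), where chance gives 10%, and all 30 called miRNAs were among them. Against 11 higher and 19 lower here, the split was 5 and 14 with median centring, 1 and 14 with 75th percentile centring, 4 and 32 with the authors' processed values, 2 and 24 with the median of spots and 1 and 17 on the high-background arrays alone, and no miRNA was called with no normalization. Of the named rises, 75th percentile centring ended all but miR-153 (adjusted p 0.0603 to 0.28), median centring ended miR-883, miR-298, miR-32 and miR-142-5p (0.0577 to 0.0949), the median of spots ended all 8 (0.0522 to 0.31), and either centring ended the fall of miR-483 (0.0647 and 0.0838). miR-122 was at -2.59 (adjusted p = 0.0261) with the authors' processed values. Falls did not outnumber rises with signal span as a covariate (57 higher and 46 lower) or with array weights (46 and 46). The count was 18 without replicate 1 and 13 without replicate 3 at 0 h, and 12 and 19 without replicates 1 and 2 at 24 h. miR-26a, miR-125b-5p, let-7c, let-7d, let-7f, let-7a and miR-153 stayed past the threshold without each of the 6 arrays in turn. Without replicate 3 at 0 h the test was missed by miR-126 (-1.28, adjusted p = 0.0653), let-7b (-0.84, adjusted p = 0.0545) and miR-145 (-0.87, adjusted p = 0.0968), the last also without replicate 1 at 24 h (adjusted p = 0.0616). miR-483 was lost without 4 of the 6 arrays (highest adjusted p = 0.165), and each of the 7 named rises below miR-153 without 2 to 6 of them (highest adjusted p = 0.173).

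**Figure D3:**
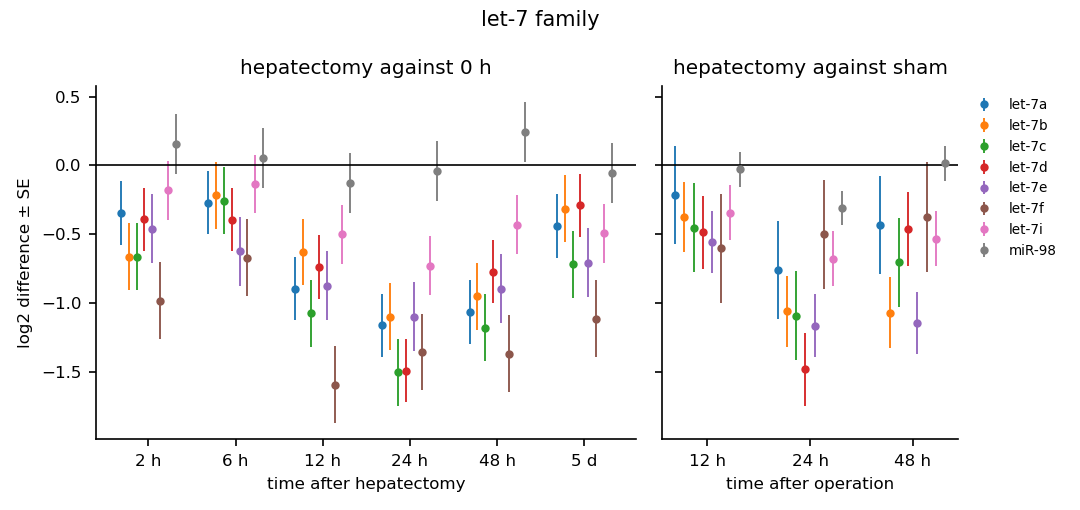
Log2 difference (vertical axis, points with SE bars) of the 8 measured let-7 members at 6 times after hepatectomy against 0 h and at 3 times against sham, n = 3 arrays per group. At 24 h against 0 h the list median was -1.13 and 7 members fell. At 12 h against sham the list median of -0.41 became 0.33 with no normalization, below the median of all miRNAs in that setting.

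At 48 h, 14 miRNAs fell and 2 rose against 0 h. miR-483 (log2 difference -1.38, SE 0.33, adjusted p = 0.0196, n = 3 per group), let-7f (-1.37, SE 0.28, adjusted p = 0.00997), miR-125b-5p (-1.23, SE 0.28, adjusted p = 0.0149), let-7c (-1.18, SE 0.24, adjusted p = 0.00997) and let-7a (-1.07, SE 0.23, adjusted p = 0.0113) fell most. The rises were miR-489 (0.60, SE 0.16, adjusted p = 0.033) and miR-204* (0.55, SE 0.13, adjusted p = 0.0233). By list, 5 of 8 let-7 members fell, and 6 adjusted over the list alone (median -0.92, camera adjusted p = 3.91e-07, adjusted p = 0.201 with an estimated correlation and 0.018 by fry). The miR-30 list was lower as a set (median -0.52, camera adjusted p = 0.0135) with 1 of 5 members lower over the list alone, as was the miR-29 list of collagen regulators (median -0.58, camera adjusted p = 0.0251) with 1 of 3. The endothelial and mesenchymal list had the same camera adjusted p with a median of -0.35, which changed sign with no normalization, and 2 of 8 members lower over the list alone. These 3 lists had an adjusted p = 0.301 with an estimated correlation and 0.0662 by fry. The miR-23/24/27 list (median -0.50, camera adjusted p = 0.0251) had 0 members lower over the list alone, and an adjusted p = 0.384 with an estimated correlation and 0.208 by fry. Over 5 scalings the medians were -1.96 to -0.54 for let-7, -1.28 to -0.36 for miR-30, -1.25 to -0.16 for miR-29 and -1.06 to -0.27 for miR-23/24/27.

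Of the rest of the fixed set at 48 h, miR-26a was at -0.96 (SE 0.28, adjusted p = 0.0517), miR-122 at -0.76 (0.517), miR-21 at -0.62 (0.518), miR-223 at -0.37 (0.471), miR-17-5p at -0.22 (0.639) and miR-16 at -0.05 (0.934). miR-221 was at 0.23 (adjusted p = 0.471), miR-1 at 0.21 (0.649), miR-222 at 0.19 (0.639) and miR-34a at 0.12 (0.671). Of 388 miRNAs, 62 had an unadjusted p under 0.05, and 70 (18.0%) did not overlap, where chance gives 10%. Against 2 higher and 14 lower here, the split was 0 and 12 with either centring, which ended both rises (adjusted p 0.0502 to 0.202), 0 and 16 with only the compared groups, 0 and 4 on the high-background arrays alone, 0 and 1 with the authors' background-subtracted values and 0 and 0 with no normalization, but 18 and 20 with signal span as a covariate and 16 and 29 with array weights. miR-26a passed under 7 of the other 15 settings (lowest adjusted p = 0.0103, with array weights). The count of 16 was 0 without replicate 1 at 0 h, 6 without replicate 3 at 0 h and 4 without replicate 1 at 48 h. let-7f and let-7c missed the test without replicate 1 at 0 h (adjusted p = 0.0608 for both), and miR-483, miR-125b-5p and let-7a without any 1 of those 3 arrays (highest adjusted p = 0.101). The rises were lost without 4 (miR-204*) and all 6 arrays (miR-489) in turn, with adjusted p up to 0.125.

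At 5 d, miR-532-3p fell against 0 h (log2 difference -0.93, SE 0.19, adjusted p = 0.031, n = 3 per group). It was the 1 call among 388 miRNAs, 53 of which had an unadjusted p under 0.05. Here too a deviation of the 0 h arrays would give the same fall, since miR-532-3p differed little among the later times. The let-7 list was lower as a set (median -0.47, camera adjusted p = 0.000365, adjusted p = 0.803 with an estimated correlation and 0.346 by fry, and -1.22 to -0.38 over 5 scalings). None of its members passed over all miRNAs, and 3 fell adjusted over the list alone. Of the fixed set, miR-223 was at -0.47 and let-7a at -0.44, both with adjusted p = 0.395, and miR-26a at -0.31 (adjusted p = 0.642), miR-17-5p at -0.27 (0.615) and miR-34a at -0.27 (0.407). miR-16 was at 0.69 (adjusted p = 0.486), miR-222 at 0.15 (0.8), miR-221 at 0.06 (0.927), miR-122 at 0.02 (0.987), miR-21 at -0.13 (0.956) and miR-1 at -0.13 (0.899). Groups did not overlap for 63 miRNAs (16.2%), where chance gives 10%. The count was 0 without replicate 1 or 3 at 0 h and without replicate 2 or 3 at 5 d, and 2 without replicate 2 at 0 h. It was also 0 with median centring (miR-532-3p at -0.91, adjusted p = 0.0666), with 75th percentile centring (-0.95, adjusted p = 0.051), with no normalization (adjusted p = 0.922) and with the authors' background-subtracted values (adjusted p = 0.171), and miR-532-3p missed the test with the authors' processed values (-1.80, adjusted p = 0.172). With array weights 28 were higher and 28 lower, and with signal span as a covariate 21 and 21.

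Sham laparotomy was followed at 12, 24 and 48 h, with no sham array at 0 h. No miRNA passed the test among 680. Against 12 h, miR-22 was at 0.70 (SE 0.17, adjusted p = 0.249, n = 3 per group) at 24 h and 0.78 (SE 0.17, adjusted p = 0.424) at 48 h, and miR-497, which shares the miR-15/16 seed, at 0.66 (SE 0.15, adjusted p = 0.249) and 0.56 (SE 0.15, adjusted p = 0.541). miR-322* was at 0.47 (SE 0.10, adjusted p = 0.249) at 24 h and miR-9, a neural miRNA, at -0.32 (SE 0.09, adjusted p = 0.541) at 48 h. Over the 3 times, the smallest adjusted p, that of miR-22, miR-322* and miR-497, was 0.528. The let-7 list rose as a set at 24 h (median 0.69, camera adjusted p = 5.88e-06) with 3 members higher adjusted over the list alone, and at 48 h (median 0.77, camera adjusted p = 5.05e-08) with 6. These calls had adjusted p = 0.285 and adjusted p = 0.255 with an estimated correlation, and the medians were positive under all 5 scalings (0.69 to 1.36 and 0.77 to 1.28). The mean signal span of the sham arrays was 0.99 at 12 h, 1.71 at 24 h and 1.45 at 48 h, so span differed between the same times as let-7. The miR-15/16 (adjusted p 0.0177 and 0.0176 at 24 and 48 h), endothelial (0.0219 and 0.0176), miR-17/20/93 (0.0284 and 0.0192) and, at 24 h, miR-29 (0.0214) lists passed with camera. None passed with an estimated correlation (smallest adjusted p = 0.285 at 24 h and 0.255 at 48 h). limma called 0 of 680, with 45 at an unadjusted p under 0.05 over the 3 times, 61 at 24 h and 45 at 48 h, and 2 over the 3 times with the replicate number as a block.

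Hepatectomy was set against sham at matched times to separate loss of liver tissue from surgery, with the limit that chip layout differed in the same way. At 12 h, miR-151, from an intron of the focal adhesion kinase gene Ptk2, was lower after hepatectomy (log2 difference -1.10, SE 0.18, adjusted p = 0.000465, n = 3 per group). miR-532-3p (-0.75, SE 0.18, adjusted p = 0.0322) was lower too, as was the dimmer miR-352 (-0.76, SE 0.18, adjusted p = 0.0322), named after its value was seen because the count is small. The call of miR-532-3p was lost under every other scaling. It was at -0.48 (adjusted p = 0.196) with median centring, -0.66 (0.0686) with 75th percentile centring and -1.35 (0.124) with the processed values. With each table on its own it was at -0.23 (0.373). With no normalization it was at 0.24 (0.558), below the median of all miRNAs there. miR-202, a gonadal miRNA, was higher (0.53, SE 0.12, adjusted p = 0.0322). The miR-23/24/27 list was lower as a set (median -0.72, camera adjusted p = 0.0244, adjusted p = 0.271 with an estimated correlation and 0.0172 by fry), with 4 of 5 members lower adjusted over the list alone and 0 over all miRNAs. Median centring ended this call (camera adjusted p = 0.196), and the median was -1.62 to -0.17 over 6 scalings. The let-7 list was not called (median -0.41, camera adjusted p = 0.119), and its median was 0.33 with no normalization, below the median of all miRNAs there. Among the 11 fixed miRNAs, miR-223 was at -0.62 (adjusted p = 0.0833), miR-26a at -0.34 (0.32), let-7a at -0.22 (0.789), miR-222 at -0.19 (0.673) and miR-34a at -0.12 (0.692). miR-122 was at 0.47 (adjusted p = 0.167), miR-16 at 0.22 (0.513), miR-1 at 0.18 (0.685), miR-21 at 0.16 (0.909), miR-17-5p at 0.06 (0.917) and miR-221 at -0.00 (0.992). The value of miR-122 was 0.00 without replicate 1 of sham at 12 h, on which it was not the brightest miRNA. With no normalization miR-122 was at 0.56, and under the other 4 scalings at -0.56 to -0.03, with no call. With each table processed on its own, miR-26a was at -1.51 (adjusted p = 0.000127, and -1.96 to -0.49 with no call under the other 4 scalings), miR-16 at -1.09 (0.0271, and -1.64 to -0.16 with no call) and miR-17-5p at 0.62 (0.0267), and miR-223 was at -2.42 (adjusted p = 0.0194) with the authors' processed values. The median of all miRNAs was itself positive with each table on its own.

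The 4 calls at 12 h, 1 higher and 3 lower, were made among 376 miRNAs, 75 of which had an unadjusted p under 0.05, and 99 (26.3%) did not overlap, where chance gives 10%. No miRNA was called with median centring, where miR-151 was at -0.86 (adjusted p = 0.0825). The split was 0 and 2 with 75th percentile centring and with no background correction, 0 and 1 with the authors' background-subtracted values, 1 and 1 with the median of spots, 148 and 0 with no normalization, and 146 and 14 with each table processed on its own. It was 9 and 12 with array weights, 8 and 10 with signal span as a covariate, 14 and 14 without the 4 weak hepatectomy arrays and 4 and 3 with only the compared groups. The count was 2 without replicate 1, and 1 without replicate 2 or 3, of hepatectomy at 12 h, and 1 without replicate 2 of sham at 12 h. miR-151 stayed past the threshold without each of the 6 arrays, miR-202 was lost without 4 (highest adjusted p = 0.134) and miR-532-3p without 5 (highest adjusted p = 0.162). miR-151 also lost its call with no normalization (-0.13, adjusted p = 0.747).

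At 24 h, 26 miRNAs were lower and 17 higher after hepatectomy than after sham. let-7d (log2 difference -1.49, SE 0.27, adjusted p = 0.000677, n = 3 per group), miR-27b (-1.48, SE 0.30, adjusted p = 0.00228), miR-29a (-1.43, SE 0.33, adjusted p = 0.00394), miR-23a (-1.43, SE 0.21, adjusted p = 0.000157) and miR-125b-5p (-1.37, SE 0.30, adjusted p = 0.00299) were the lowest. let-7e (-1.17, adjusted p = 0.0016), let-7c (-1.09, 0.0251), let-7b (-1.06, 0.00699), miR-23b (-0.97, 0.0143) and miR-30c (-0.95, 0.0172) followed. The star strand let-7i* (1.27, SE 0.22, adjusted p = 0.000677), miR-148b-3p, a relative of the liver-enriched miR-148a (1.08, SE 0.18, adjusted p = 0.000604), and miR-878 (1.08, SE 0.23, adjusted p = 0.00246) were the highest. miR-20b-3p (0.98, adjusted p = 0.0135), miR-335 from the imprinted Mest gene (0.91, 0.005), miR-153 (0.79, 0.00299), miR-883 (0.75, 0.0176), miR-410 of the Dlk1-Dio3 cluster (0.66, 0.0271), miR-32 (0.64, 0.0143) and miR-322, with the miR-15/16 seed (0.62, 0.00198), were also higher.

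By list, 5 of 8 let-7 members were lower than in sham at 24 h, and 7 adjusted over the list alone (median -0.91, camera adjusted p = 2.5e-05, adjusted p = 0.259 with an estimated correlation and 0.00445 by fry). The median was negative under all 6 scalings compared (-2.64 to -0.78). In the miR-23/24/27 list, 4 of 5 were lower both ways (median -0.97, camera adjusted p = 0.00223, adjusted p = 0.114 with an estimated correlation and 0.00026 by fry), and the median was -3.22 to -0.97 over 6 scalings. In the miR-30 list, 2 of 5 were lower (median -0.40, camera adjusted p = 0.0655, 0.0071 with median centring, and 0.0287 by fry), with adjusted p = 0.434 with an estimated correlation. fry also gave the star strands an adjusted p of 0.0316 (camera 0.494), and an adjusted p = 0.481 with an estimated correlation. In the fixed set, let-7a was at -0.76 (adjusted p = 0.172), miR-21 at -0.61 (0.413), miR-223 at -0.49 (0.114), miR-26a at -0.47 (0.099), miR-17-5p at -0.39 (0.211) and miR-34a at -0.16 (0.493). miR-221 was at 0.23 (adjusted p = 0.322), miR-1 at 0.15 (0.703), miR-222 at 0.12 (0.786), miR-16 at 0.09 (0.814) and miR-122 at 0.00 (1). In the joint fit each rank has one value on every array, and miR-122 was the brightest miRNA on 29 of the 30 arrays, which fixes its differences at 24 and 48 h at 0.00, so these are not measured values. miR-16 lay at ranks 2 to 6 and miR-26a at ranks 2 to 13, so their differences cannot exceed the gaps between the shared values at those ranks. With each table processed on its own, miR-122 was at -1.38 and miR-16 at -1.65, both past the threshold, as they were with either centring and with the authors' processed values, and miR-221 (0.64, adjusted p = 0.000364) and miR-222 (0.46, 0.0307) passed too. The median of all miRNAs was itself positive with each table on its own. miR-21 was past it under 4 scalings (-2.93 to -1.08) and let-7a with either centring and the authors' processed values (-2.20 to -1.44). miR-26a, the value of which was nearest to 0 in the joint fit among 6 scalings, was past the threshold in the other 5, at -3.46 with median centring, -3.39 with 75th percentile centring, -3.11 with no normalization, -4.38 with the authors' processed values and -2.35 with each table on its own.

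Of 376 miRNAs at 24 h, 97 had an unadjusted p under 0.05 and 140 (37.2%) did not overlap, where chance gives 10%, with 41 of the 43 called among them. Against 17 higher and 26 lower here, the split was 9 and 50 with median centring, 16 and 49 with 75th percentile centring, 0 and 16 with no normalization, 6 and 41 with the authors' processed values, and 177 and 32 with each table on its own. It was 66 and 57 with array weights, 24 and 20 with the authors' background-subtracted values, and 19 and 20 with signal span as a covariate. The count was 19 without replicate 2 and 21 without replicate 3 of sham at 24 h. Of the 20 miRNAs named, let-7d, miR-27b, miR-29a, miR-23a, miR-125b-5p, let-7e, let-7i*, miR-148b-3p, miR-878, miR-335, miR-153 and miR-322 stayed past the threshold without each of the 6 arrays. The others, let-7b, let-7c, miR-23b, miR-30c, miR-20b-3p, miR-883, miR-410 and miR-32, were lost without 1 to 4 of them (adjusted p up to 0.223). Either centring ended the calls of let-7i*, miR-148b-3p, miR-335 and miR-322 (adjusted p 0.0803 to 0.687), and median centring those of miR-878, miR-20b-3p and miR-883 (0.0797 to 0.221). The authors' processed values ended those of miR-148b-3p, miR-878, miR-20b-3p, miR-335, miR-153, miR-883 and miR-322 (adjusted p 0.0763 to 0.302). No normalization ended every named rise (adjusted p 0.0915 to 0.433), and the falls of miR-27b, let-7e, let-7c and let-7b (0.0599 to 0.151). With median and 75th percentile centring, let-7i* was at 0.24 and 0.31 and miR-148b-3p at 0.37 and 0.44. miR-335 was at 0.42 and 0.50 and miR-322 at 0.21 and 0.29.

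At 48 h, 8 miRNAs were lower and 1 higher than in sham. let-7e (log2 difference -1.15, SE 0.23, adjusted p = 0.00444, n = 3 per group), miR-23a (-1.10, SE 0.21, adjusted p = 0.00444), let-7b (-1.07, SE 0.26, adjusted p = 0.0188), miR-378, from an intron of Ppargc1b (-0.85, SE 0.20, adjusted p = 0.0151), and miR-361 (-0.70, SE 0.14, adjusted p = 0.00444) were the lowest, and miR-489 was higher (0.70, SE 0.17, adjusted p = 0.0191). In the let-7 list, 2 of 8 members were lower, and 3 adjusted over the list alone (median -0.50, camera adjusted p = 0.000884, adjusted p = 0.421 with an estimated correlation and 0.0962 by fry, and -2.17 to -0.50 over 6 scalings). In the miR-23/24/27 list, 1 of 5 was lower both ways (median -0.53, camera adjusted p = 0.019, adjusted p = 0.343 with an estimated correlation and 0.0432 by fry, and -2.09 to -0.53 over 6 scalings). The miR-30 list passed with median centring (camera adjusted p = 0.0236, and 0.321 here, with adjusted p = 0.702 with an estimated correlation). For the fixed set, let-7a was at -0.43 (adjusted p = 0.63), miR-223 at -0.36 (0.433), miR-21 at -0.35 (0.775), miR-222 at -0.17 (0.755) and miR-16 at -0.09 (0.845). miR-34a was at 0.39 (adjusted p = 0.157), miR-221 at 0.21 (0.531), miR-1 at 0.10 (0.856), miR-26a at 0.09 (0.858) and miR-17-5p at 0.05 (0.927), with miR-26a at -1.51 when each table was processed on its own. miR-16 was past the threshold with 75th percentile centring (-2.02, adjusted p = 0.0297), with the authors' processed values (-2.21, 0.00917) and with each table on its own (-1.44, 0.00626), as were let-7a with the processed values (-2.01, 0.0194) and miR-221 (0.54, 0.00329) and miR-34a (0.66, 0.00143) with each table on its own. In that last setting the median of all miRNAs was itself positive. miR-122, fixed at 0.00 by the joint quantile normalization, was at -1.40 to -0.81 under the other 5 scalings (adjusted p = 0.173 to 0.436). Of 376 miRNAs, 55 had an unadjusted p under 0.05 and 67 (17.8%) did not overlap, where chance gives 10%. Against 1 higher and 8 lower here, the split was 0 and 25 with the authors' processed values and 156 and 21 with each table on its own, 1 and 17 with median centring, 1 and 32 with 75th percentile centring, 12 and 17 with array weights, 3 and 10 without the 4 weak hepatectomy arrays and 3 and 8 with no background correction, and no miRNA was called with no normalization or with only the compared groups. miR-378 missed the test with median centring and with each table on its own (adjusted p = 0.101 and 0.107), miR-361 with the processed values and with each table on its own (0.0783 and 0.104) and miR-489 with the processed values (0.0735). The count of 9 was 0 without replicate 1 and 25 without replicate 2 of hepatectomy at 48 h, and 5 and 3 without replicates 1 and 2 of sham at 48 h. let-7e, miR-23a and miR-361 missed the test without replicate 1 of hepatectomy (adjusted p = 0.0559 for each), and miR-378, miR-489 and let-7b without 2, 3 and 4 of the 6 arrays (adjusted p up to 0.112).

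**Figure D4:**
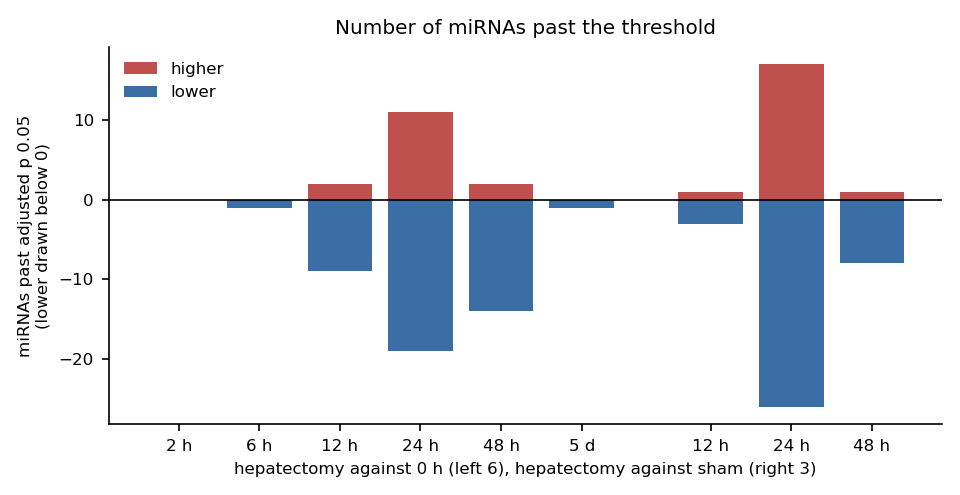
Number of miRNAs past an adjusted p of 0.05 (vertical axis, bars from 0, higher upward and lower downward) in each comparison (horizontal axis), from limma with 3 arrays per group. Against 0 h the counts were 11 at 12 h, 30 at 24 h and 16 at 48 h, and against sham they were 4, 43 and 9.

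The change between times was compared between operations, which removes a constant offset between chip layouts. Whether probes of one name have identical sequences in both layouts is not given in the sources used here, and a layout difference that changes with level would not be removed. From 12 to 24 h, no single miRNA passed, and the smallest p values were those of miR-29a, which represses collagens (log2 difference in change -1.45, SE 0.46), miR-22 (-1.06, SE 0.36) and miR-125b-5p (-1.21, SE 0.42), each with adjusted p = 0.753 and n = 3 per group. The let-7 list went lower after hepatectomy relative to sham (median -0.58, 7 of 8 members negative, camera adjusted p = 0.00105), with adjusted p = 0.43 with an estimated correlation, 0.55 by fry and 0 members past the test either over all miRNAs or over the list alone. Its median was negative under all 6 scalings (-2.07 to -0.58). The let-7 change within sham, with the span of its arrays, enters this value. In the sham fit it was a median of 0.69 from 12 to 24 h, enough in size to give the whole difference. An effect of hepatectomy therefore cannot be told apart from the change within sham. With median centring, camera also called the miR-23/24/27 (adjusted p = 0.00247), miR-15/16 and endothelial (both 0.0299) lists lower and the Dlk1-Dio3 list higher (0.0397). With an estimated correlation on the quantile-normalized values these 4 had adjusted p = 0.546, 0.882, 0.43 and 0.616. The miR-15/16 list was at a median of 0.08 here (camera adjusted p = 0.541) and negative under the other 5 scalings (down to -1.18). The Dlk1-Dio3 median was negative with no normalization (-0.32), though above the median of all miRNAs there. Of the fixed set, miR-21 was at -0.77, let-7a at -0.54, miR-122 at -0.47, miR-17-5p at -0.46, miR-222 at 0.31 and miR-221 at 0.23, and miR-26a, miR-16, miR-223 and miR-34a were at -0.13, -0.13, 0.13 and -0.04, each with adjusted p = 0.983. miR-1 was at -0.02 (adjusted p = 0.992). The value of miR-122 was 0.00 without replicate 1 of sham at 12 h. Under the other 5 scalings miR-122 was at -2.82 to -1.35, miR-26a at -2.61 to -0.84 and miR-16 at -2.46 to -0.56, with no call (adjusted p = 0.314 to 0.987). limma called 0 of 376, with 18 at an unadjusted p under 0.05, 1 without replicate 2 of hepatectomy at 12 h, and 1, miR-29a (adjusted p = 0.0122), with only the compared groups.

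From 24 to 48 h, miR-148b-3p (-0.92, SE 0.26, adjusted p = 0.565), miR-153 (-0.77, SE 0.25, adjusted p = 0.839) and let-7i* (-0.89, SE 0.32, adjusted p = 0.926) had the smallest p values and did not pass. The let-7 list was at a median of 0.24 (camera adjusted p = 0.303), and no list passed. Among the 11 fixed miRNAs, miR-26a was at 0.56, miR-34a at 0.55 and miR-17-5p at 0.44, each with adjusted p = 0.926. let-7a was at 0.33 and miR-16 at -0.18 (adjusted p = 0.967 for both), miR-222 at -0.29 (0.96), miR-21 at 0.26 and miR-223 at 0.13 (0.979 for both), miR-1 at -0.05 (0.984) and miR-221 at -0.02 (0.997). miR-122 has no measured value here, since the joint quantile normalization fixes it at 0.00, and it was at 0.57 to 1.44 under the other 5 scalings (adjusted p = 0.958 to 0.998). miR-26a was at 0.84 to 1.98 and miR-16, of the opposite sign here, at 0.21 to 1.18 under the same 5, with no call. limma called 0 of 376, with 18 at an unadjusted p under 0.05.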

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

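Chosen only after the results were seen were the tests with signal span as a covariate, with background level as a block, on the high-background arrays alone and without the 4 weak hepatectomy arrays, the test of the rises under the planned centrings, whose bound was set with the values known, and the count of members past the threshold against the other times.

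The let-7 family was singled out because its change from 12 to 24 h differed between operations in a test of the difference itself, with a median of -0.58 over 8 members (camera adjusted p = 0.00105). With an estimated correlation between members the difference had adjusted p = 0.43, and 0.55 by fry, and camera at the preset correlation also called let-7 in 26% of simulated datasets with no change for 24 h against 0 h. Within sham the list rose by a median of 0.69 from 12 to 24 h, while mean signal span went from 0.99 to 1.71. The sham arrays could thus give the whole difference, and an effect of hepatectomy cannot be told apart from them.

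The 19 miRNAs that fell at 24 h against 0 h had a median of -1.10 (SE of a member 0.243). With background level as a block all 19 were still lower and past the threshold (median -1.08). This argues against background level as the whole cause, though on the high-background arrays alone, with fewer arrays, only 14 of the 19 passed (median -0.97). With signal span as a covariate all 19 were lower and past the threshold as well (median -0.96). That covariate raised the number of calls over all miRNAs, so members staying called is weak evidence. Spans were 1.46 to 2.34 at 0 h and 0.78 to 1.69 at 24 h and overlapped little. The covariate therefore cannot decide whether span was the cause. Leaving out the weak arrays left 24 h with replicate 1 alone, where the median was -1.20 and no test is given. If the 3 arrays at 0 h alone stood apart, 24 h should match the mean of 2 h, 6 h and 5 d. Against that mean the median was -0.58 (quartiles -0.88 to -0.29), narrowly past the bound set in advance and within the members' spread, while 6 members still passed lower, miR-26a (-1.72), miR-126 (-1.26), let-7d (-1.13), miR-125b-5p (-1.05), let-7c (-0.96) and let-7a (-0.81). This argues against the 0 h arrays as the whole cause for those 6, and for the other falls a share from those arrays cannot be told apart from regeneration at 24 h, which may also contribute.

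The 11 miRNAs that rose at 24 h, 3 of them below the median level, had a median of 0.58 (SE of a member 0.153). Whether any of the 11 stood above background was not tested. With signal span as a covariate 10 were still higher and past the threshold (median 0.63). As for the falls, this cannot decide whether span was the cause. With 75th percentile centring the median was 0.45 (SE 0.170) and 1 was called, and with median centring it was 0.57 and 5 were called in the higher direction. The lower quartile of the 11 changes was at least 0.41 under both centrings, above 0.29, the bound of 0.5 of the median. Both centrings shift a whole array and leave its signal range unchanged, so this cannot decide whether scaling was the cause in whole or part. With the authors' processed values 2 of the 11 were called higher, and with no normalization 0. On the high-background arrays alone, with fewer arrays, 1 of the 11 was still called (median 0.56). Leaving out the weak arrays left 24 h with replicate 1 alone, where the median was 0.68 and no test is given.

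The 43 miRNAs that differed between hepatectomy and sham at 24 h may carry an offset between chip layouts. A pure offset would give the same difference at 12 and 48 h, and the median ratio of that mean difference to the one at 24 h was 0.604 (quartiles 0.436 to 0.741), with 43 of 43 of the same sign. Because the 43 were picked for passing at 24 h, even a pure offset would tend to look smaller at 12 and 48 h. The ratio alone therefore cannot decide. A test of the 24 h difference against the mean of 12 and 48 h called 0 miRNAs in limma (20 at an unadjusted p under 0.05, smallest adjusted p = 0.527), so layout and operation cannot be told apart for these 43. With signal span as a covariate 32 were still past the threshold. Span was taken over 388 names on hepatectomy arrays and 680 on sham arrays, so it is not the same measure in both operations. This count therefore does not decide whether span was the cause. Loss of liver tissue, which the design names, stays open, and the differences in change, which a constant layout offset does not enter, called 0 of 376 miRNAs from 12 to 24 h and from 24 to 48 h.

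Comparisons of 3 against 3 arrays allow 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 0 and 0 at 2 h (10 splits as large), 1 and 1 at 6 h (2 splits as large), and 11 and 0 at 12 h, 30 and 0 at 24 h, 16 and 0 at 48 h and 1 and 0 at 5 d. Against sham they were 4 and 1 at 12 h, 43 and 0 at 24 h and 9 and 3 at 48 h, the real split being the 1 split as large in each of these 7 comparisons. For the F test over 7 hepatectomy times, 5 of 100 splits gave 9 calls or more (highest other 98), so chance was not excluded. Splits with 98, 82, 23 and 14 calls had 86.3%, 56.0%, 68.7% and 65.6% of the variation in signal span between their groups, against 25.5% for the real one, which points to a structure of the arrays. Which structure was not settled, since splits with 64.1%, 59.3%, 59.1%, 56.1% and 54.3% gave 0 calls, and the splits with 82, 23 and 14 calls also had 59.6% of the variation in background level between groups (19.2% for the real one), as did 4 splits with 0 calls. For the sham F test, and for both differences in change, 100 of 100 splits gave at least the real 0 calls, with 8, 1 and 3 as the highest others. For the 19 list calls, 16 of 100 splits gave as many (highest other 37), so chance was not excluded.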

How the results depend on the processing

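Chosen after seeing the data were the background block, the high-background arrays alone, the fit without the 4 weak hepatectomy arrays and signal span as a covariate. All other settings were planned. The settings below are those that moved a count by over 1.5 times, and for each the cause was not tested unless stated. Signal over background may limit all of them, since 4 hepatectomy arrays and replicate 2 of sham at 12 h had spans of 0.57 to 0.85. No chip or slide block was run because none is named in the sources used here, and the fit of only the compared groups gives no value for an F test.

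Counts are called miRNAs, in the order named. Against 0 h at 2, 6, 12, 24 and 48 h, 5 d and over all times, array weights gave 10, 14, 62, 92, 45, 56 and 87, and against sham at 12, 24 and 48 h 21, 123 and 29. Signal span as a covariate gave 4, 13, 62, 103, 38, 42 and 38, and 18 against sham at 12 h. With no normalization, counts at 6, 12, 24 and 48 h, 5 d and over all times were 0, and against sham 148, 16 and 0. No normalization placed the median of all miRNAs at 0.19 to 0.47 against 0 h, at 0.64, 0.26 and 0.48 against sham, and at -0.39 and 0.21 for the differences in change. Each table on its own gave 160, 209 and 177 against sham, with medians of all miRNAs at 0.32, 0.36 and 0.36. Centring on the 75th percentile gave 1 at 2 h, 6 at 12 h, 15 at 24 h, 0 at 5 d and 2 over all times, and 2, 65 and 33 against sham, with the median of all miRNAs between -0.12 and -0.06 at 2, 6, 12 and 48 h and 5 d, at -0.26 and -0.10 against sham at 12 and 48 h, and at 0.22 for the change from 12 to 24 h. Median centring gave 6 at 12 h, 19 at 24 h, 0 at 5 d and 4 over all times, and 0 at 12 h and 18 at 48 h against sham.

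The background block gave 1 at 2 h, 27 at 12 h, 46 at 24 h, 27 at 48 h and 10 at 5 d. The high-background arrays alone gave 0 at 6 h, 18 at 24 h and 4 at 48 h, with fewer arrays. As 2 h and 5 d held 1 such array each, no count is given for them or over all times. Without weak arrays there were 1 at 2 h and 2 at 5 d, and 28 against sham at 12 h. No count is given at 24 h, where replicate 1 alone was left. The authors' background-subtracted values gave 0 at 6 h, 1 at 12 h, 1 at 48 h, 0 at 5 d and 0 over all times, and 1 and 4 against sham at 12 and 48 h. The authors' processed values gave 0 at 6 h, 17 at 12 h and 10 at 48 h, and 7 and 25 against sham at 12 and 48 h. No background correction gave 1 at 2 h, 7 at 12 h and 2 against sham at 12 h. The median of spots gave 2 and 5 against sham at 12 and 48 h. Only the compared groups gave 2 at 2 h, 0 at 6 h and 28 at 12 h, 7 and 0 against sham at 12 and 48 h, and 1 for the change from 12 to 24 h. Testing only miRNAs above the median level gave 1 at 2 h and 2 at 5 d, with fewer miRNAs tested. Over 198 list tests, not counting those between sham times, camera made 19 calls, all lower, at the preset correlation and 0 with an estimated one (11 at an unadjusted p under 0.05). fry made 12 calls, 9 lower and 3 higher, 8 of them among the 19.

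With each array left out in turn, counts ranged from 0 to 4 at 2 h, 0 to 4 at 6 h, 1 to 17 at 12 h, 12 to 30 at 24 h, 0 to 19 at 48 h, 0 to 2 at 5 d and 3 to 14 over all times. Against sham they ranged from 1 to 6, 19 to 40 and 0 to 25, for differences in change from 0 to 1 and 0 to 0, and for the sham F test from 0 to 0. Of the values of named miRNAs in these fits, 1157 stayed on their side of the threshold, 138 lost the call and 7 gained one. The sign reversed for 67 of the 1302, none of them called in either fit.

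Deviations of same-numbered arrays correlated at a mean r of 0.0816 after hepatectomy (-0.765 to 0.783, 50.8% of 63 pairs over 0.1, -0.0388 for different numbers) and 0.121 after sham (-0.194 to 0.370, 55.6% of 9 pairs over 0.1, -0.0604 for different numbers). Of the arrays, 11 of 21 and 4 of 9 were closest to their own number. Because not every pair lay over 0.1 and the labels name no shared animal, the numbers were not taken to pair the arrays, though the means hint at some shared deviation. With the replicate block the counts were 0, 1, 9, 38, 16 and 1 against 0 h, 4, 46 and 10 against sham, 0 and 0 for the differences in change, and 2 for the sham F test.

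Where either fit made a call, the sign changed for miR-1 at 24 h against 0 h with span as a covariate (-0.35) and, against sham, for miR-532-3p at 12 h with no normalization (0.24). The latter value still lay below the median of all miRNAs with no normalization. With each table on its own, values against sham were 0.34 for miR-221 and -1.09 for miR-16 at 12 h, -1.38 for miR-122 and -1.65 for miR-16 at 24 h, and -1.51 for miR-26a at 48 h. The value of miR-221 lay near the positive median of all miRNAs in that setting. At 24 h against sham, miR-122 was at -2.61 with median centring, -2.54 with 75th percentile centring and -2.72 with processed values. miR-16 was at -2.97, -2.90 and -3.28 in these and -2.62 with no normalization. miR-26a at 48 h was at -2.07, -2.11 and -2.40. For miR-122, at rank 1 on 29 of 30 arrays, quantile normalization fixes the differences at 24 and 48 h at 0.00 by construction. For miR-16, at ranks 2 to 6, and miR-26a, at ranks 2 to 13, it limits the differences to the gaps between the shared values at those ranks. How much of the gap between scalings this limit gives was not tested.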

Other observations

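The test that counted each cluster of neighbouring genes once was chosen only after the result over all pairs was seen, and the groups below outside the fixed lists were picked after their values were seen.

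The miR-99/100 and miR-125 families, which share primary transcripts with let-7 members in mammals, stood outside the fixed lists. At 24 h against 0 h, miR-99a (-1.01) and miR-100 (-0.93) fell, as did miR-125b-5p (-1.59) and miR-125a-5p (-0.56), n = 3 per group and each past limma's adjusted threshold of 0.05. At 48 h miR-99a (-0.92), miR-100 (-0.89), miR-125b-5p (-1.23) and miR-125a-5p (-0.68) were past it too, against the same 3 arrays at 0 h.

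A hypothesis written down before its test was run was that miRNAs with neighbouring genes change alike at 24 h against 0 h, as shared transcripts would give. Over 594 pairs of neighbours of unlike families within 50 kb, from 142 miRNAs, the mean absolute difference in log2 change was 0.335, against 0.404 for names permuted within 5 classes of level (one-sided permutation p = 0.0275), which is consistent with the hypothesis. Of those pairs, 362 came from 1 cluster. With each of 29 clusters counted once, the means were 0.420 and 0.498 (one-sided permutation p = 0.063), a gap of similar size that did not pass the threshold, so the hypothesis stays open.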
